A study of Homo sapiens with 24 samples.

How the data were processed

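Total RNA from P493 cells was labelled as biotinylated cRNA and hybridised to Illumina expression beadchips, per the labels' protocols. The labels also state extraction with Trizol, clean-up with a DNase I step and a quality check on a Bioanalyzer. There were 24 arrays in 8 groups of 3, from 2 treatments (none or MST-312) and 4 release times (0, 4, 8 and 24 h). The labels number the replicates but do not say whether they were separate cultures. No chip or scan identifier is given in the sources used here, so a chip effect was not analysed here.

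The deposited raw table holds, per the file headers, an intensity and a detection p-value for each of 47322 probes on each array. A series value table holds the authors' processed intensity for the same arrays. Its values were linear, ranked the probes of each array exactly as that array's raw column did (rank correlation 1), and had nearly equal medians, from 138.28 to 138.37, as after quantile normalization, although the method is not given in the sources used here. The raw table was the source of the values below, and the authors' processed values were an alternative. They gave the same median change over all genes in every comparison as quantile normalization without background correction, another alternative, so these are not separate checks. Probes were named through the platform annotation. It gave 1 symbol to 30113 probes, several symbols to 8 and none to 17201. A match by gene ID covered 30074 of the named probes and changed no symbol.

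Raw intensities were background-corrected by normexp with parameters derived from the detection p-values, given an offset of 16, quantile-normalised and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p below 0.05 on all 3 arrays of at least 1 group were kept, which left 17882, of which 13518 had 1 symbol. The probe with the highest mean over all arrays stood for its gene, giving 10246 genes, 2603 of which had more than 1 passing probe. The text gives another passing probe's value for some genes whose probes differed. Passing probes without a single symbol numbered 4364 and were not named. The share of detected probes lay between 34.3% and 38.0% per array and the mean raw intensity between 527 and 764. With 3 arrays per group, the number of arrays limits the precision.

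One limma model with 8 group means was fitted to all 24 arrays (16 residual degrees of freedom, 3.78 prior degrees of freedom). The 13 comparisons were MST-312 against untreated at each time, each later time against 0 h within each treatment, and the difference between the treatments' changes since 0 h (the interaction) at 4, 8 and 24 h. Benjamini-Hochberg adjustment ran over all genes of a comparison, with an adjusted p below 0.05 taken as changed. Every p given for a gene is limma's adjusted p, two-sided. Genes were named by a rule. It took MYC and TERT, and the 10 largest rises and 10 largest falls among changed genes in each comparison of MST-312 with untreated cells, in each 24 h release comparison and in the 24 h interaction. Outside the interaction, these had to have no overlap between the arrays of both groups. The text gives a part of them. From each gene list the rule took up to 4 changed members with the largest change, and up to 2 that moved the other way by at least 1.5-fold. Symbols of unnamed loci and open reading frames were left out. Where a gene was not detected on any array of the dimmer group, the ratio is given as "at least N-fold", from the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own.

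There were 30 gene lists, 29 of them with at least 5 tested members. Their shift against all other genes was tested with camera at a preset correlation of 0.01, adjusted over the lists, then with an estimated correlation. A further test, fry, asks whether the genes of a list move on balance one way, not whether they differ from other genes. Each list's count is given over all genes tested and adjusted over the list alone. The lists covered ribosome biogenesis, textbook MYC-activated genes, genes described as repressed by MYC, purine and pyrimidine synthesis, glycolysis, cytosolic and mitochondrial ribosomal proteins, cytosolic tRNA synthetases, translation initiation factors, G1/S and DNA replication, G2/M and mitosis, homologous recombination and Fanconi genes, and p53, NRF2, NF-kB and hypoxia-inducible factor targets. The others held ATF4 and integrated stress response genes, the ER unfolded protein response, heat shock, iron handling, interferon-stimulated genes, cholesterol and fatty acid synthesis, oxidative phosphorylation, telomerase and telomere genes, apoptosis, B cell identity, plasma cell differentiation, and markers of T cells, of monocytes and macrophages, and of epithelial cells and fibroblasts. Some genes stand on more than 1 list.

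The replicate numbers were checked for pairing. Arrays with the same number deviated together from their group means between the treatments at one time (correlations from 0.11 to 0.38, all above 0.1). Between times they did so for replicate 3 (from 0.12 to 0.28) and mostly for replicate 1 (from 0.06 to 0.20), but not for replicate 2 (from -0.15 to 0.06), and replicates 1 and 3 lay on opposite sides of the first residual component in all 8 groups. The fit without the number as a block was kept, and the block was an alternative. Other alternatives were median scaling, cyclic loess, quantile normalization without background correction, normexp with an offset of 50, the authors' processed values, no filter, a detection p below 0.01, the mean of passing probes, only the groups of the comparison, an intensity trend, array weights and leaving out each array. Normalization and filter were kept when an array was left out. The comparisons, lists, naming rule and these alternatives were fixed before the data were examined, and 2 further alternatives were added afterwards.

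The steps were tested on simulated data for 10246 genes with 200 changed. In the 24 h treatment comparison, log2 changes of 0.5, 1 and 2 were recovered in 50.7%, 91.0% and 100% of changed genes, with 7 false calls among 168. In the 24 h interaction, 17.9%, 79.1% and 97.0% were recovered, with 9 false calls among 138. A shifted list was called in both, and none of the 29 other lists was (0 in each). The simulated genes varied independently of each other, on the normalised scale. The runs therefore did not test false list calls among correlated genes, nor the normalization. Far fewer genes were changed than the 6333 and 3068 called in the real 24 h treatment comparison and interaction. The Benjamini-Hochberg cut-off depends on the share of changed genes, so the recovered shares and false calls need not hold there. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.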

Results

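Gene expression was measured in P493 cells, a human B cell line whose MYC transgene is shut off by tetracycline, with and without MST-312, a small-molecule inhibitor of telomerase. The series states that treated cells were held with MST-312 and tetracycline for 48 h and then moved to tetracycline-free medium that still held MST-312. Cells were taken 0, 4, 8 and 24 h after this release, with 3 arrays for each treatment and time, 24 in all. Whether the 3 came from separate cultures is not stated, so the SE, SD and p-values below may not cover variation between cultures. The tetracycline schedule of the untreated cells is not given in the sources used here. Their release is assumed below, and a difference in schedule cannot be told apart from MST-312 in any comparison between the treatments. Between 16254 and 17959 probes were detected per array, and 10246 genes were tested. The design asks how MST-312 changes expression at each time and how it changes the response to release.

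MYC rose after release in both treatments, and its brightest probe already gave a strong signal at 0 h. In untreated cells at 0 h this probe was detected on 3 of 3 arrays (mean raw intensity 15800) and was brighter than the probes of 98.7% of genes. Brightness also depends on the probe, so this rank does not show how abundant the transcript of MYC was. In untreated cells its level went from 14.05 ± 0.11 at 0 h to 14.84 ± 0.15 at 4 h (mean log2 intensity ± SD, n = 3), and its log2 change since 0 h was 0.79 at 4 h, 0.94 at 8 h and 0.70 at 24 h (SE 0.10 each, adjusted p = 2.51e-06, 1.78e-07 and 5.79e-06). With MST-312 the changes were 1.08, 1.20 and 1.31 (SE 0.10, adjusted p = 8.87e-08, 1.42e-08 and 1.89e-09). A second, dimmer MYC probe gave larger changes, 0.96, 1.25 and 1.05 in untreated cells and 1.16, 1.34 and 1.39 with MST-312. Raw means of the brightest probe reached 38590, so that saturation was not excluded. MST-312 cells differed from untreated cells in MYC by -0.23 at 0 h (adjusted p = 0.0625), 0.06 at 4 h (0.669) and 0.03 at 8 h (0.834), and were higher by 0.38 at 24 h (adjusted p = 0.00331). The difference at 24 h did not pass with median scaling (0.34, adjusted p = 0.0931), and that at 0 h did pass with the replicate number as a block (adjusted p = 0.0263), with 8 other settings of the model or the normalization (adjusted p from 0.0214 to 0.0489 over all 9), and without untreated 24 h replicate 2 (0.0480) or MST-312 24 h replicate 3 (0.0483). Among these settings, the authors' values and quantile normalization without background correction gave the same result (-0.227, adjusted p = 0.0444) and are not separate checks. The second probe gave treatment differences of -0.10, 0.10, -0.00 and 0.24 at 0, 4, 8 and 24 h, with the opposite sign at 8 h. The files do not say whether the probes read the transgene, the resident gene or both. Both probes of TERT, the catalytic subunit of telomerase, were undetected on all 24 arrays, with group mean raw intensities from 73.6 to 122.6, so a difference in its transcript was not measurable here.

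**Figure D1:**
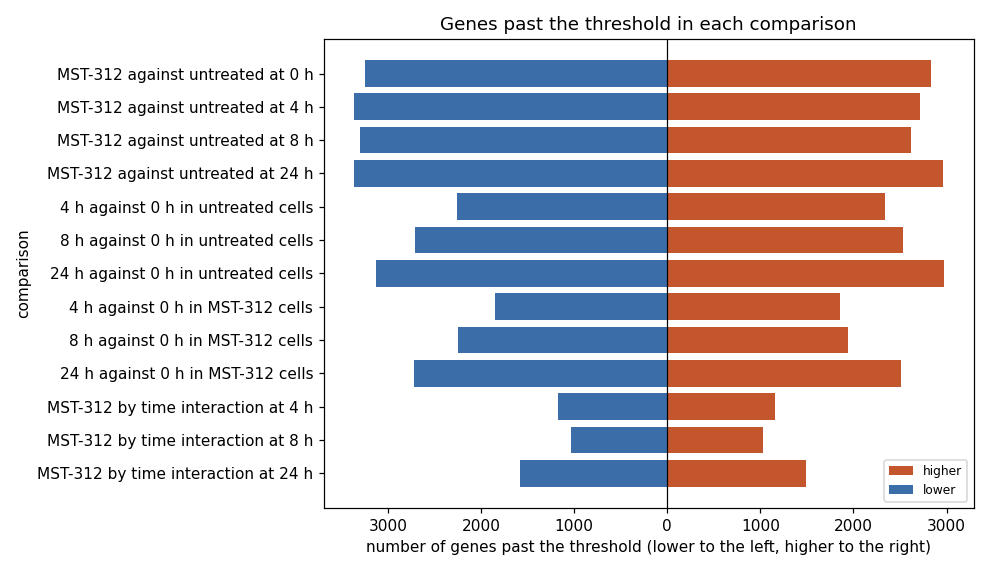
Number of genes past the threshold in each of the 13 comparisons, lower to the left and higher to the right of 0 (horizontal axis, number of genes of 10246 tested). The treatment comparisons hold between 5909 and 6333 genes and the interactions between 2060 and 3068.

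At 0 h, before release, MST-312 cells had far lower transcripts of interferon-stimulated genes than untreated cells. IFI44L differed by -6.99 ± 0.08 (log2, SE, adjusted p = 5.95e-23), MX1, which encodes an antiviral GTPase, by -5.63 ± 0.14, and IFIT1, whose product binds viral RNA, by -4.62 ± 0.09 (adjusted p = 2.74e-17 and 6.17e-19, n = 3 per group). A second probe gave -3.35 for IFI44L and -2.52 for IFIT1. All 17 tested interferon-stimulated genes fell (17 adjusted over the list alone, median -3.14, camera adjusted p = 9.33e-15). In the other direction, genes of the ER unfolded protein response and of the ATF4 stress pathway rose. DNAJB9, an ER co-chaperone, was higher by 2.80 ± 0.07, and DDIT3, the stress transcription factor CHOP, by 1.88 ± 0.11 (adjusted p = 7.44e-17 and 8.12e-12).

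The ER list had 14 of 15 members higher and 1 not passed (14 adjusted over the list alone, median 0.92, camera adjusted p = 9.27e-07), among them XBP1 at 2.26 and PDIA4 at 1.77. Of the 19 ATF4 genes, 16 rose, 1 fell and 2 did not pass (16 and 1 adjusted over the list alone, median 1.17, camera adjusted p = 1.17e-08). PSAT1, an enzyme of serine synthesis, rose by 2.38 and ATF5 by 1.96, while PSPH, of the same pathway as PSAT1, fell by 0.95 (-0.44 by a second probe). Among p53 targets 13 rose, 2 fell and 8 did not pass (14 and 2 adjusted over the list alone, median 0.50, camera adjusted p = 0.000960). CCNG1 and PPM1D rose by 1.32 and 1.23, though a second CCNG1 probe gave 0.31. BAX, which promotes apoptosis, fell by 1.66, but another probe gave -0.16. Of 17 genes of cholesterol and fatty acid synthesis 12 rose, 1 fell and 4 did not pass (12 and 1 adjusted over the list alone, median 0.56, camera adjusted p = 0.000960), with the squalene epoxidase SQLE at 1.14. Mitotic genes were lower, with 26 of 29 down and 3 not passed (26 adjusted over the list alone, median -1.26, camera adjusted p = 2.01e-08), for example CCNB1, the mitotic cyclin, by -2.07 and BIRC5, or survivin, by -2.01.

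Of 38 genes of G1/S and DNA replication 28 fell, 2 rose and 8 did not pass (28 and 2 adjusted over the list alone, median -0.77, camera adjusted p = 1.05e-05, but adjusted p = 0.0513 with an estimated correlation). With members undetected in the dimmer group at their bounds, that median was -0.69. MCM4, a subunit of the replicative helicase, fell by 1.92. Glycolysis (14 fell, 2 rose, 2 did not pass, 14 and 3 adjusted over the list alone, median -0.50, camera adjusted p = 0.00602) and oxidative phosphorylation (41 fell, 6 rose, 29 did not pass, 41 and 6 adjusted over the list alone, median -0.29, camera adjusted p = 0.00154) were called lower, with adjusted p = 0.329 and 0.429 with an estimated correlation. PFKL, a phosphofructokinase subunit, fell by 2.05, and UQCRC2, of respiratory complex III, by 1.76. Of 19 B cell identity genes 11 fell, 2 rose and 6 did not pass (11 and 2 adjusted over the list alone, median -0.41, camera adjusted p = 0.0405, adjusted p = 0.329 with an estimated correlation), CD40 by -1.59 and CD74 by -1.25. Other probes gave -0.97 for CD40 and as low as -2.78 for CD74. Of 18 cytosolic tRNA synthetases 11 rose, 4 fell and 3 did not pass (11 and 4 adjusted over the list alone, median 0.46, camera adjusted p = 0.0405, adjusted p = 0.294 with an estimated correlation). TARS1 and GARS1 rose by 1.44 and 1.26. In all, 2834 genes were higher and 3246 lower at 0 h. The B cell shift was not called with median scaling (adjusted p = 0.119), and the tRNA synthetase shift was not called with median scaling, cyclic loess or only the arrays of the comparison (0.0768, 0.0613 and 0.0627), with the replicate number within each time as a block (0.0507), or without MST-312 0 h replicate 2 (0.0567). With median scaling the median over all genes was itself -0.13, -0.33, -0.28 and -0.17 at 0, 4, 8 and 24 h in the treatment comparisons, so that changes under that setting stand relative to these values.

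Among single genes, NFIX, a transcription factor, rose most at 0 h, by 5.29 ± 0.23 (adjusted p = 1.80e-13), and the histone gene H4C5 by 4.25 ± 0.15 (3.95e-15). SNORD46, a small nucleolar RNA that guides methylation of ribosomal RNA, rose by 4.09 ± 0.20 (1.10e-12). Many other histone genes and small nucleolar RNAs were higher too, with causes left open below. HLA-DOB, a subunit of the class II modulator HLA-DO, fell by 4.03 ± 0.17 (7.86e-14) and ANXA4, an annexin, by 3.91 ± 0.30 (6.03e-10).

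At 4 h of release the stress genes were still higher and the heat shock genes had become lower in MST-312 cells. PPP1R15A, which brings a phosphatase to the initiation factor eIF2, was higher by 2.27 ± 0.09 (adjusted p = 1.86e-14) and DDIT3 by 2.23 ± 0.11 (6.38e-13). HSPH1 and HSPA8, both cytosolic chaperone genes, had log2 changes of -1.40 ± 0.08 and -1.11 ± 0.10 (adjusted p = 1.68e-11 and 4.44e-09). RELB, a subunit of NF-kB, rose by 1.94 ± 0.11 (3.88e-12). In total 2716 genes were higher and 3367 lower.

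Of the ATF4 genes 17 rose, 1 fell and 1 did not pass at 4 h (17 and 1 adjusted over the list alone, median 1.52, camera adjusted p = 3.83e-10). Of the ER list 13 rose and 2 did not pass (13 adjusted over the list alone, median 0.79, camera adjusted p = 1.98e-06). Of 15 heat shock genes 12 fell, 1 rose and 2 did not pass (12 and 1 adjusted over the list alone, median -0.68, camera adjusted p = 0.000415). Interferon-stimulated genes fell in 16 of 17 cases (16 adjusted over the list alone, median -1.62, camera adjusted p = 1.63e-09). Mitotic genes fell in 27 of 29 cases (28 adjusted over the list alone, median -1.62, camera adjusted p = 6.61e-10). With undetected members at their bounds, the interferon and mitotic medians were -1.58 and -1.54. Of 18 NF-kB targets 12 rose, 2 fell and 4 did not pass (12 and 2 adjusted over the list alone, median 0.53, camera adjusted p = 0.0116, adjusted p = 0.154 with an estimated correlation), among them ICAM1 at 1.37 and CCL3 at 1.34. Of 23 p53 targets 10 rose, 3 fell and 10 did not pass (10 and 3 adjusted over the list alone, median 0.19, camera adjusted p = 0.0331, adjusted p = 0.0678 with an estimated correlation), a median that turned to -0.21, without a call, with median scaling. MDM2 rose by 1.47. The p53 shift was also not called with only the arrays of the comparison (0.0605) or without untreated 4 h replicate 1 (0.0566).

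At 8 h the ATF4 genes ATF5 and SLC3A2, the latter a subunit of an amino acid transporter, were higher by 2.31 ± 0.11 and 1.78 ± 0.09 (adjusted p = 1.06e-12 and 1.28e-12), with 2.46 for SLC3A2 by a second probe. UBE2C, which drives exit from mitosis, fell by 2.90 ± 0.19 and TOP2A, a topoisomerase of dividing cells, by 2.48 ± 0.17 (5.39e-11 and 2.01e-10). Mitotic genes were lower in 26 of 29 cases (27 adjusted over the list alone, median -1.52, camera adjusted p = 2.56e-10), and the median was -1.41 with undetected members at their bounds. There were 2614 genes higher and 3295 lower.

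The ATF4 list at 8 h held 15 rises, 1 fall and 3 not passed (15 and 1 adjusted over the list alone, median 1.13, camera adjusted p = 3.53e-07, adjusted p = 0.0546 with an estimated correlation) and the ER list 12 rises and 3 not passed (13 adjusted over the list alone, median 0.56, camera adjusted p = 5.18e-05). Interferon-stimulated genes fell in 14 cases, rose in 1 and did not pass in 2 (14 and 1 adjusted over the list alone, median -1.13, camera adjusted p = 1.64e-06), with a median of -1.04 at the bounds. Heat shock genes gave 12 falls, 1 rise and 2 not passed (12 and 1 adjusted over the list alone, median -0.74, camera adjusted p = 0.000349). p53 targets gave 13 rises, 3 falls and 7 not passed (13 and 3 adjusted over the list alone, median 0.34, camera adjusted p = 0.00691). Of 75 mitochondrial ribosomal proteins 51 fell, 4 rose and 20 did not pass (52 and 4 adjusted over the list alone, median -0.36, camera adjusted p = 0.000138, adjusted p = 0.165 with an estimated correlation), MRPL23 by -1.94 and MRPL16 by -1.44.

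By 24 h of release, genes of DNA replication and mitosis were much lower in MST-312 cells than in untreated cells. CDC45, a subunit of the replicative helicase, was at least 15.6-fold lower and undetected with MST-312 (adjusted p = 6.95e-18), and MCM10, another replication factor, was at least 11.4-fold lower (1.42e-12) on 1 probe, while another gave -2.58 (log2). TOP2A, UBE2C and the mitotic kinase CDK1 fell by 3.77 ± 0.17, 3.70 ± 0.19 and 3.63 ± 0.18 (adjusted p = 2.46e-13, 9.02e-13 and 1.07e-12, n = 3 per group), with -3.01 for CDK1 by a second probe. DDIT3 was higher by 2.96 ± 0.11 and SLC3A2 by 2.28 ± 0.09 (8.93e-15 and 2.27e-14), with 3.24 for SLC3A2 by a second probe. HRK, a BH3-only gene of apoptosis, rose by 2.35 ± 0.11 (3.02e-13).

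Of the 38 G1/S and replication genes 34 fell and 4 did not pass (34 adjusted over the list alone, median -1.61, camera adjusted p = 5.79e-15). Of 29 mitotic genes 28 fell and 1 did not pass (28 adjusted over the list alone, median -1.97, camera adjusted p = 1.16e-12). Interferon-stimulated genes stayed lower, with 14 falls and 3 not passed (14 adjusted over the list alone, median -0.91, camera adjusted p = 1.73e-05), MX1 by -4.06 and IFI6 by -2.31 (-1.60 by a second probe). At the bounds of undetected members the 3 medians were -1.50 for G1/S and replication, -1.95 for mitosis and -0.84 for interferon-stimulated genes. Of the p53 targets 17 rose, 2 fell and 4 did not pass (17 and 2 adjusted over the list alone, median 0.61, camera adjusted p = 0.000171), with RRM2B at 1.88 (0.83 by a second probe), MDM2 at 1.47 and AEN at 1.29. The ATF4 list had 14 rises, 3 falls and 2 not passed (14 and 3 adjusted over the list alone, median 1.09, camera adjusted p = 0.000171, adjusted p = 0.204 with an estimated correlation). Of 14 homologous recombination and Fanconi genes 11 fell, 2 rose and 1 did not pass (11 and 2 adjusted over the list alone, median -1.28, camera adjusted p = 0.00102, adjusted p = 0.125 with an estimated correlation), among them the nuclease gene EXO1, at least 6.68-fold lower on 1 probe, while another gave -1.43 (log2).

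Metabolic lists were also called lower at 24 h, none of them with an estimated correlation. Of 76 oxidative phosphorylation genes 55 fell, 1 rose and 20 did not pass (56 and 1 adjusted over the list alone, median -0.41, camera adjusted p = 1.91e-06, adjusted p = 0.256 with an estimated correlation). Of the mitochondrial ribosomal proteins 43 fell, 9 rose and 23 did not pass (43 and 9 adjusted over the list alone, median -0.27, camera adjusted p = 0.00103, adjusted p = 0.256 with an estimated correlation). Purine and pyrimidine synthesis had 15 falls and 4 not passed (15 adjusted over the list alone, median -0.46, camera adjusted p = 0.00102, adjusted p = 0.256 with an estimated correlation), with PRPS2 at -1.32 and PFAS at -1.25. For glycolysis there were 14 falls, 3 rises and 1 not passed (14 and 3 adjusted over the list alone, median -0.67, camera adjusted p = 0.00268, adjusted p = 0.291 with an estimated correlation). TPI1 fell by 1.26, and SLC2A3, a glucose transporter, rose by 0.86. Of 30 textbook MYC-activated genes 16 fell, 3 rose and 11 did not pass (16 and 3 adjusted over the list alone, median -0.31, camera adjusted p = 0.0294, adjusted p = 0.363 with an estimated correlation). E2F2 and CDC25A, which act in entry to S phase, fell by 3.38 and 2.48 (-1.39 by a second CDC25A probe), and TFRC, the transferrin receptor, rose by 0.84. Of 11 genes described as repressed by MYC 9 rose, 1 fell and 1 did not pass (9 and 1 adjusted over the list alone, median 0.64, camera adjusted p = 0.00397, adjusted p = 0.0637 with an estimated correlation), among them HBP1 at 1.73 and FOXO3 at 1.18 (0.70 by a second probe).

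Several lists were not called at 24 h. Where the count adjusted over the list alone differs from that over all genes, it is given in brackets. The ER list had 8 rises [9], 3 falls and 4 not passed (median 0.29, camera adjusted p = 0.0517). Ribosome biogenesis had 8 rises [7], 10 falls and 22 not passed (median -0.05, 0.984), with the test's direction opposite in sign to the median. Heat shock had 2 rises, 7 falls and 6 not passed (median -0.26, 0.310). Telomerase and telomere genes had 4 rises, 6 falls and 11 not passed (median -0.02, 0.848). STN1, a subunit of the telomere-capping CST complex, fell by 1.34, but another probe gave -0.08. NHP2, of telomerase and other H/ACA particles, fell by 0.93. Cytosolic ribosomal proteins gave 5 rises and 15 falls [14] among 74 (median -0.01, camera adjusted p = 0.747). Translation initiation factors gave 7 and 9 among 31 (median 0.01, mean -0.03, 0.966) and tRNA synthetases 8 and 4 among 18 (median 0.08, 0.591). Apoptosis genes gave 7 rises and 4 falls among 19 (median 0.09, 0.424) and NF-kB targets 6 and 3 among 18 (median 0.12, 0.310). NRF2 targets gave 3 and 5 among 14 (median -0.04, 0.966) and hypoxia-inducible factor targets 9 and 3 among 20 (median 0.19, 0.285). Iron handling gave 3 and 5 [6] among 11 (median -0.35, -0.12 at the bounds, 0.778). For cholesterol and fatty acid synthesis the counts were 3 and 9 among 17 (median -0.29, camera adjusted p = 0.438). They were 4 and 10 among 19 for B cell identity (median -0.41, 0.236) and 5 and 5 among 12 for plasma cell differentiation (median 0.16, mean -0.07, 0.966). Markers of other cell types were few among the tested genes. T cell markers gave 2 falls [1] among 5 (median -0.13, -0.09 at the bounds, 0.501) and epithelial and fibroblast markers 3 rises and 2 falls among 5 (median 0.37, 0.07 at the bounds, 0.310). Of 4 tested monocyte and macrophage markers, too few for the list test, 1 rose and 2 fell. In total 2963 genes were higher and 3370 lower at 24 h.

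Across the 4 times, 1509 genes were higher with MST-312 at every time and 1919 lower at every time, against 55.4 and 112.8 if the 4 lists of changed genes were independent. The 4 lists share the cell line, the probes and the continued MST-312, so an overlap above independence was likely in advance and is not a test of persistence. The times share no arrays, but arrays with the same number deviated together between times for replicates 1 and 3 (correlations from 0.06 to 0.28). SNORD46, NFIX, H4C5 and LINC00115 stood among the 10 largest rises at each time and IFI44L among the 10 largest falls. SNORD46 and H4C5 belong to classes, small nucleolar RNAs and histone genes, of which many members were higher with MST-312, with causes left open below. At 24 h, SNORD46 rose by 5.52 ± 0.20 (adjusted p = 1.14e-14) and PLCH2, a phospholipase C, by 4.68 ± 0.12 (1.25e-16). NPRL3, a subunit of the GATOR1 complex that restrains mTORC1, fell by 4.21 ± 0.16 (1.54e-14). IFI44L was at least 9.84-fold lower and undetected with MST-312 on its brightest probe (7.10e-19), while its second probe gave a log2 change of -0.62.

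**Figure D2:**
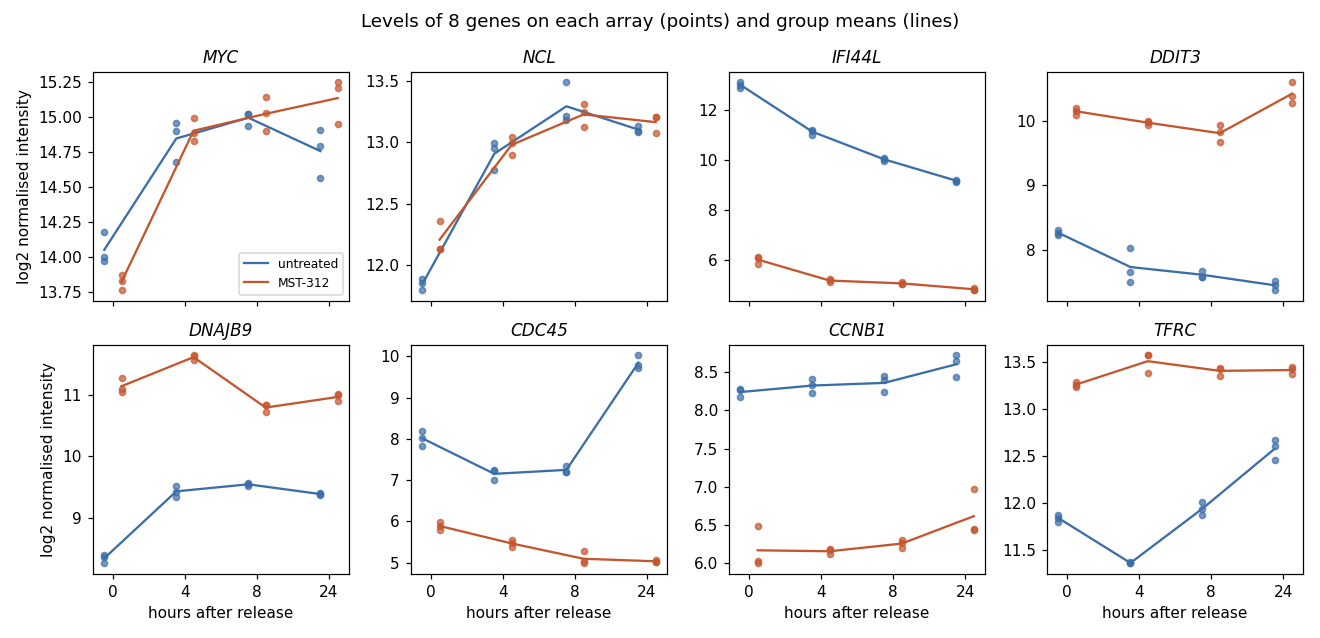
Log2 normalised intensity of 8 genes (vertical axes, which differ in range and do not start at 0) against hours after release, in untreated and MST-312 cells. Points are single arrays (n = 3) and lines join group means. MYC and NCL, a nucleolar protein gene, rise after release in both treatments, and IFI44L and CDC45 lie lower and DDIT3 higher with MST-312 at each time.

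After release of untreated cells, genes of ribosome production, nucleotide synthesis and DNA replication rose, and interferon-stimulated and B cell genes fell. That these cells were held in tetracycline and then released is assumed, since their schedule is not given in the sources used here. No arrays of cells kept without release to the later times were present, so release cannot be told apart from time in culture. At 24 h against 0 h, RRS1 and NOLC1, both nucleolar factors, rose by 1.90 ± 0.08 and 1.88 ± 0.11 (log2, SE, adjusted p = 1.82e-13 and 7.56e-12), PFAS, an enzyme of purine synthesis, by 1.98 ± 0.08 (2.66e-14) and CDC25A by 2.50 ± 0.16 (7.15e-11, 1.02 by a second probe). IFIT3 fell by 3.44 ± 0.15 (1.52e-13, as little as -2.04 by other probes), EGR1, an immediate-early transcription factor, by 4.25 ± 0.12 (4.03e-16), and CD72, a B cell surface receptor, changed by -3.37 ± 0.24 (1.93e-10). KISS1R, a neuropeptide receptor gene, had the largest rise, 3.17 ± 0.13 (6.46e-14).

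Of 40 ribosome biogenesis genes 38 rose and 2 did not pass at 24 h (38 adjusted over the list alone, median 1.31, camera adjusted p = 1.36e-17). Of 30 MYC-activated genes 27 rose and 3 did not pass (27 adjusted over the list alone, median 1.27, camera adjusted p = 2.01e-12). All 19 genes of purine and pyrimidine synthesis rose (19 adjusted over the list alone, median 1.19, camera adjusted p = 3.56e-11). In G1/S and DNA replication 34 of 38 rose and 4 did not pass (34 adjusted over the list alone, median 1.02, camera adjusted p = 2.01e-12), with a median of 0.92 at the bounds. UNG and GINS2 rose by 2.02 and 1.97. At 8 h the G1/S and replication list had had 5 rises and 16 falls (5 and 16 adjusted over the list alone, median -0.19, camera adjusted p = 0.0818). Mitotic genes at 24 h had 8 rises, 2 falls and 19 not passed (8 and 2 adjusted over the list alone, median 0.23, camera adjusted p = 0.210). Mitochondrial ribosomal proteins rose in 62 of 75 cases, with 1 fall and 12 not passed (64 and 1 adjusted over the list alone, median 0.58, camera adjusted p = 2.01e-12). Heat shock genes had 12 rises, 1 fall and 2 not passed (12 and 1 adjusted over the list alone, median 0.98, camera adjusted p = 3.92e-05), HSPA8 at 1.30 and HSPA6 at -1.16 (-0.61 by a second probe). tRNA synthetases had 14 rises, 1 fall and 3 not passed (14 and 2 adjusted over the list alone, median 0.66, camera adjusted p = 0.000146) and translation initiation factors 21, 1 and 9 (21 and 1 adjusted over the list alone, median 0.46, camera adjusted p = 0.000175). Cholesterol and fatty acid synthesis had 12 rises, 1 fall and 4 not passed (12 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 0.00345), SCD at 1.67 and FASN at 1.46.

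All 17 interferon-stimulated genes fell at 24 h of release in untreated cells (17 adjusted over the list alone, median -2.36, camera adjusted p = 6.99e-14), as they had at 4 h (median -1.58, 1.59e-15) and 8 h (median -2.42, 1.99e-16). Of the B cell genes 17 fell and 2 did not pass (17 adjusted over the list alone, median -1.37, camera adjusted p = 2.99e-09), FCER2 by -2.11 and POU2AF1, a coactivator of immunoglobulin genes, by -1.98. NF-kB targets fell in 12 of 18 cases (12 adjusted over the list alone, median -0.77, camera adjusted p = 0.000160), CCL3 by -3.02. Of the p53 targets 13 fell, 1 rose and 9 did not pass (13 and 1 adjusted over the list alone, median -0.47, camera adjusted p = 0.00633). Of the apoptosis genes 12 fell, 1 rose and 6 did not pass (13 and 2 adjusted over the list alone, median -0.64, camera adjusted p = 0.00265). Of the genes described as repressed by MYC 7 fell, 1 rose and 3 did not pass (7 and 1 adjusted over the list alone, median -0.69, camera adjusted p = 0.00441), TXNIP by -2.27 and NDRG1 by -1.88.

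Some shifts of untreated cells at 24 h were called at the preset correlation only. They were oxidative phosphorylation (52 rises, 1 fall, 23 not passed, 53 and 1 adjusted over the list alone, median 0.47, camera adjusted p = 5.63e-09, adjusted p = 0.0825 with an estimated correlation), homologous recombination (10, 1 and 3, 10 and 1 adjusted over the list alone, median 0.50, 0.00255, adjusted p = 0.0747 with an estimated correlation) and glycolysis (12, 4 and 2, 12 and 4 adjusted over the list alone, median 0.66, 0.00633, adjusted p = 0.211 with an estimated correlation). NRF2 targets (9, 1 and 4, 9 and 1 adjusted over the list alone, median 0.61, 0.00441) and the ER list (10, 1 and 4, 10 and 1 adjusted over the list alone, median 0.34, 0.00527) had adjusted p = 0.125 and 0.0855 with an estimated correlation. The ATF4 list (10, 5 and 4, 12 and 5 adjusted over the list alone, median 0.38, 0.0374) and telomerase and telomere genes (10, 2 and 9, 10 and 2 adjusted over the list alone, median 0.15, 0.0249) had adjusted p = 0.326 and 0.225 with an estimated correlation. DKC1, the dyskerin of telomerase and of H/ACA particles, rose by 1.53 and TINF2, a shelterin gene, fell by 1.06. Cytosolic ribosomal proteins were called higher (29 rises, 1 fall, 44 not passed, 27 and 1 adjusted over the list alone, median 0.12, camera adjusted p = 0.00370), but not with cyclic loess (median 0.03, adjusted p = 0.301). The ATF4 shift was not called with cyclic loess (0.0585) or only the arrays of the comparison (0.0595), nor was the telomere shift in the latter (0.0731). In untreated cells 2343 genes rose and 2262 fell at 4 h, 2536 and 2706 at 8 h, and 2972 and 3130 at 24 h.

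In MST-312 cells, ribosome biogenesis and nucleotide synthesis genes again rose and B cell genes fell after release, while replication genes showed no common shift. RRP12 and RRS1, both factors of ribosome assembly, rose by 2.09 ± 0.11 and 1.78 ± 0.08 at 24 h (adjusted p = 4.56e-12 and 1.13e-12), and NME1, a nucleoside diphosphate kinase gene, by 1.56 ± 0.09 (1.63e-11, 2.22 by another probe). CD72 fell by 2.93 ± 0.24 and FCRL2, a B cell Fc receptor-like gene, by 3.02 ± 0.08 (2.95e-09 and 3.41e-16). A second FCRL2 probe gave -1.30. TOP2A fell by 2.72 ± 0.17 (1.01e-10). CLIC3, a chloride channel gene, rose by 2.99 ± 0.10 (9.61e-15).

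Of the ribosome biogenesis genes 36 rose and 4 did not pass (37 adjusted over the list alone, median 1.09, camera adjusted p = 2.08e-18). Of the nucleotide synthesis genes 18 rose and 1 did not pass (18 adjusted over the list alone, median 0.77, camera adjusted p = 4.19e-09). MYC-activated genes had 22 rises, 1 fall and 7 not passed (24 and 2 adjusted over the list alone, median 0.84, camera adjusted p = 1.39e-08), with E2F2 falling by 2.58. Mitochondrial ribosomal proteins had 51 rises, 3 falls and 21 not passed (52 and 4 adjusted over the list alone, median 0.47, camera adjusted p = 2.56e-09) and heat shock genes 12, 1 and 2 (13 and 1 adjusted over the list alone, median 0.89, camera adjusted p = 9.42e-06). Of the B cell genes 17 fell, 1 rose and 1 did not pass (17 and 1 adjusted over the list alone, median -0.97, camera adjusted p = 2.12e-09). NF-kB targets fell in 13 of 18 cases (14 fell and 1 rose adjusted over the list alone, median -0.61, camera adjusted p = 0.000383). Interferon-stimulated genes fell in 11, rose in 1 and did not pass in 5 (11 and 1 adjusted over the list alone, median -0.50, camera adjusted p = 0.00494). At the bounds, the interferon median was -0.27 and that of nucleotide synthesis 0.72. G1/S and replication genes had 12 rises, 8 falls and 18 not passed (12 and 8 adjusted over the list alone, median 0.07, camera adjusted p = 0.397), and mitotic genes 14 falls, 1 rise and 14 not passed (14 and 1 adjusted over the list alone, median -0.27, camera adjusted p = 0.00518, adjusted p = 0.0823 with an estimated correlation).

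Other shifts of MST-312 cells at 24 h were called at the preset correlation only. NRF2 targets (11 rises and 3 not passed, 11 adjusted over the list alone, median 0.51, camera adjusted p = 0.000212), oxidative phosphorylation (39 rises, 6 falls, 31 not passed, 39 and 6 adjusted over the list alone, median 0.30, 1.19e-05) and translation initiation factors (16, 3 and 12, 16 and 3 adjusted over the list alone, median 0.30, 0.00944) had adjusted p = 0.0823, 0.197 and 0.173 with an estimated correlation. SRXN1 and NQO1, which counter oxidants, rose by 1.32 and 1.03. Glycolysis (10, 4 and 4, 10 and 4 adjusted over the list alone, median 0.38, 0.0366), telomerase and telomere genes (10, 5 and 6, 10 and 5 adjusted over the list alone, median 0.25, 0.0329) and tRNA synthetases (8, 2 and 8, 8 and 2 adjusted over the list alone, median 0.14, 0.0394) had adjusted p = 0.322, 0.248 and 0.196. The tRNA synthetase shift was not called with the mean of passing probes (0.0633) or without MST-312 0 h replicate 1 (0.0546), MST-312 24 h replicate 1 (0.0519) or MST-312 24 h replicate 3 (0.0513). Counts of changed genes were 1852 up and 1848 down at 4 h, 1939 and 2252 at 8 h, and 2508 and 2719 at 24 h.

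**Figure D3:**
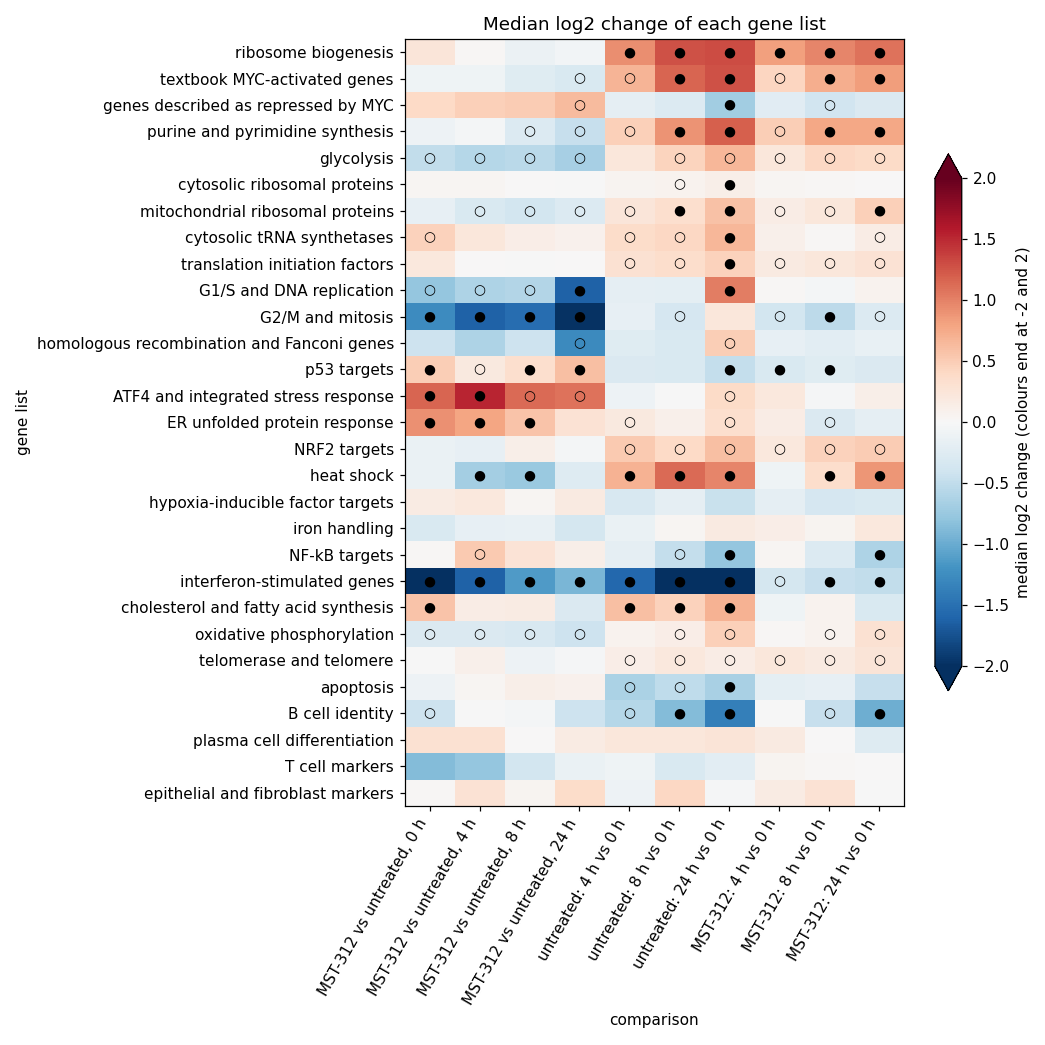
Median log2 change (colour, ending at -2 and 2) of the 29 tested gene lists (vertical axis) in 10 comparisons (horizontal axis). Filled circles mark shifts called by camera at both the preset and the estimated correlation, open circles those called at the preset correlation only. Interferon-stimulated genes are lower in every column, and ribosome biogenesis is higher after release in both treatments.

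The 24 h responses of the 2 treatments mostly had the same direction in genes changed in both, and they differed in many genes. Across genes, which are not independent replicates, the slope of the MST-312 response on the untreated response was 0.55 (SD 0.0065 over the 3 replicate numbers, Pearson r = 0.669). Since a slope also falls as the correlation falls, it is not a ratio of the sizes of the 2 responses. 1782 genes rose and 1854 fell in both, against 728 and 831 for independent lists, and 162 and 132 moved in opposite directions. The 2 responses share no arrays, but arrays with the same number deviated together between the treatments at 0 h (correlations from 0.13 to 0.30) and at 24 h (from 0.14 to 0.37), which the counts for independent lists leave out. The response differed between the treatments in 2325 genes at 4 h (1152 higher and 1173 lower interaction), 2060 at 8 h (1029 and 1031) and 3068 at 24 h (1488 and 1580). With median scaling the last 2 totals were 1277 and 1929. That scaling also moved the balance at 4 and 8 h toward lower interactions, with medians over all genes of -0.194 and -0.16.

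At 24 h interferon-stimulated genes had positive and replication genes negative interactions. IFI44 changed by -3.03 in untreated cells, and its 0.45 in MST-312 cells did not pass (adjusted p = 0.128), an interaction of 3.48 ± 0.34 (log2, adjusted p = 1.86e-07). All 17 interferon-stimulated genes had a positive interaction (17 adjusted over the list alone, median 1.96, camera adjusted p = 1.50e-20). Of the G1/S and replication genes 28 had a negative interaction and 10 did not pass (29 adjusted over the list alone, median -0.84, camera adjusted p = 4.22e-17). For the mitotic genes the counts were 15 and 14 (15 adjusted over the list alone, median -0.57, camera adjusted p = 1.09e-05). E2F2 had an interaction of -2.56 ± 0.17 (1.03e-09), PSAT1 of -2.97 ± 0.12 (1.07e-12), having risen by 2.30 in untreated cells, and CDK1 of -2.27 ± 0.26 (1.61e-06, -1.17 by a second probe). MYC had a positive one of 0.61 ± 0.15 (adjusted p = 0.00351), which did not pass with median scaling (0.48, adjusted p = 0.177). Its second probe gave 0.33.

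Cholesterol and fatty acid synthesis had 14 negative interactions and 3 not passed at 24 h (15 adjusted over the list alone, median -0.76, camera adjusted p = 4.98e-08) and the ER list 9 and 6 (11 adjusted over the list alone, median -0.52, camera adjusted p = 1.65e-06). Homologous recombination had 10 and 4 (10 adjusted over the list alone, median -0.89, camera adjusted p = 3.05e-05) and plasma cell differentiation 6 and 6 (6 adjusted over the list alone, median -0.50, camera adjusted p = 0.00420). Heat shock genes had negative interactions at 4 h (10 of 15, 11 adjusted over the list alone, median -0.51, camera adjusted p = 4.62e-06) and 8 h (8 of 15, with 1 positive, 12 and 1 adjusted over the list alone, median -0.54, camera adjusted p = 7.35e-06), but were not called at 24 h (3 positive and 3 negative, also adjusted over the list alone, median -0.07, camera adjusted p = 0.689). For ribosome biogenesis 12 were negative and 28 did not pass at 24 h (12 adjusted over the list alone, median -0.23, camera adjusted p = 0.0138, adjusted p = 0.282 with an estimated correlation), and for MYC-activated genes 10 and 20 (10 adjusted over the list alone, median -0.28, camera adjusted p = 9.56e-05, adjusted p = 0.09997 with an estimated correlation).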

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

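The tests of MYC level for the interferon genes and the counts of array splits that leave 1 time unmixed were chosen only after the results were seen. The response to release differed between MST-312 and untreated cells, by the test of the difference itself, in 2325 genes at 4 h, 2060 at 8 h and 3068 at 24 h. In 100 splits of the 12 arrays within each time, 13, 11 and 14 gave as many genes, so chance is not excluded by these counts, and the highest other splits gave 7038, 4868 and 7179. Splits that leave the treatments unmixed at 1 time or both carry the treatment difference itself into the interaction, so their counts are not those of chance. All the other splits with as many genes (12, 10 and 13) were among the 21, 19 and 21 that left the treatments unmixed at 1 time or both, while the 78, 80 and 78 that mixed both times gave at most 1, 0 and 0 genes. Mixing both times puts the treatment difference into the spread, so these low counts do not show what chance would give either.

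For the comparisons of 3 arrays against 3, 1 of 10 splits gave as many genes in each, the real one, which is too few splits for a share under 0.05. The real counts of MST-312 against untreated cells were 6080, 6083, 5909 and 6333 genes at 0, 4, 8 and 24 h, and the highest other split gave 0 at each. In the 4 splits that part as many numbered pairs, the highest other also gave 0. For release of untreated cells the real counts were 4605, 5242 and 6102, with 0, 0 and 1 in the highest other split, and for release of MST-312 cells 3700, 4191 and 5227, with 1 in each. These other splits also put the real difference into the spread, so their low counts do not show what chance would give.

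Differences in the 24 h response were called for 17 lists, as medians of log2 interaction. Interferon-stimulated genes had 1.96, genes described as repressed by MYC 0.23 and apoptosis genes 0.21. The lists with negative medians were homologous recombination and Fanconi genes (-0.89), G1/S and DNA replication (-0.84), cholesterol and fatty acid synthesis (-0.76), G2/M and mitosis (-0.57), the ER unfolded protein response (-0.52) and plasma cell differentiation (-0.50). Smaller ones were purine and pyrimidine synthesis (-0.43), cytosolic tRNA synthetases (-0.30), textbook MYC-activated genes (-0.28), translation initiation factors (-0.25), ribosome biogenesis (-0.23), mitochondrial ribosomal proteins (-0.16), oxidative phosphorylation (-0.15) and cytosolic ribosomal proteins (-0.0737). With an estimated correlation 7 of the 17 were called, those of interferon-stimulated genes, homologous recombination, G1/S and replication, cholesterol and fatty acid synthesis, mitosis, the ER list and plasma cell differentiation. The other 10 were not, with adjusted p = 0.09997 with an estimated correlation for genes described as repressed by MYC, MYC-activated genes and tRNA synthetases, 0.106 for apoptosis, 0.107 for cytosolic ribosomal proteins and 0.118 for purine and pyrimidine synthesis. It was 0.282 for ribosome biogenesis, mitochondrial ribosomal proteins and translation initiation factors and 0.556 for oxidative phosphorylation. The shifts not called with some settings were those of MYC-repressed genes (median scaling, adjusted p = 0.0591), apoptosis (mean of passing probes, 0.0587), cytosolic ribosomal proteins (cyclic loess, 0.298, without untreated 24 h replicate 2, 0.0656, without MST-312 0 h replicate 2 or 3, 0.0506 and 0.0581) and oxidative phosphorylation (without MST-312 0 h replicate 2, 0.0506). Translation initiation factors were not called with cyclic loess (0.0598), with the mean of passing probes (0.0587), or without untreated 0 h replicate 1 or 3 (0.0578 and 0.0556), MST-312 0 h replicate 2 (0.0530) or MST-312 24 h replicate 2 (0.0581).

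Single genes whose 24 h response differed were MYC (log2 interaction 0.61), IFI27 (5.04), CLIC3 (4.76), OASL (3.58), IFI44 (3.48), CD1C (3.46), DDX60 (3.22), ADAMTSL2 (3.19), FNDC5 (3.08), KLK4 (2.99) and INPP1 (2.98). Negative interactions were largest in CDT1 (-3.78), PSAT1 (-2.97), CDC45 (-2.69), E2F2 (-2.56), TOP2A (-2.46), EXO1 (-2.42), GPHN (-2.39), AFF3 (-2.35), MCM10 (-2.35) and CDK1 (-2.27). Except for MYC, CLIC3, IFI44, PSAT1, E2F2, TOP2A, GPHN, AFF3 and CDK1, these genes were undetected in at least 1 of the groups, so their values depend on the level of background there. On the probes used, IFI27, CD1C, INPP1 and EXO1 were undetected with MST-312 at both 0 and 24 h, so these probes measured no MST-312 response. Second probes gave smaller interactions for MYC (0.33), OASL (1.18), EXO1 (-1.19), GPHN (-1.05) and CDK1 (-1.17). Of the 4364 detected probes without a single gene symbol, 943 were higher with MST-312 at 24 h and 649 lower, a signal outside the comparisons of named genes.

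The positive interaction of interferon-stimulated genes, limited as above by members too dim to fall as in untreated cells, starts from their low level at 0 h with MST-312, which had a list median of -3.14 against untreated cells. A single array does not account for that difference, since the median lay between -3.18 and -3.08 whichever of the 6 arrays was left out. A higher level of MYC before release could lower these genes, which fell while MYC rose in untreated cells. The MYC transcript was not higher at 0 h, with a difference of -0.23 (-0.10 by its second probe). The rise of at least 0.5 asked of this cause was set after the results were seen, from the MYC rise in these untreated cells. MYC protein was not measured here, so a cause through the protein stays open. A difference in the tetracycline schedule of the untreated cells, which is not given in the sources used here, was not tested and stays open, as does an effect of MST-312 itself.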

How the results depend on the processing

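The replicate number within each time as a block and the 2 sides of the first residual component as a block were chosen only after the data were seen. Results covered 570 values of named genes and 178 called list shifts under 38 other settings. Of the counts of changed genes, those under median scaling for the interactions at 8 h (1277 against 2060) and 24 h (1929 against 3068) moved by over 1.5 times. Across single left-out arrays these counts ran from 1739 to 2104 and from 2734 to 3123. The slope of the MST-312 response on the untreated response was 0.5317 with median scaling, and from 0.5424 (without untreated 24 h replicate 1) to 0.5566 across left-out arrays. The cause was not tested. ANTXR1 at 4 h reversed to 0.15 (adjusted p = 0.575) without the detection filter, where another, undetected probe stood for the gene. Median scaling lowered the share of higher genes among those changed to 34.1%, 20.9%, 22.6% and 32.7% in the treatment comparisons at 0, 4, 8 and 24 h, from 46.6%, 44.6%, 44.2% and 46.8%. It gave 61.8% and 58.8% for untreated cells at 4 and 8 h (50.9% and 48.4%), 32.5% for MST-312 cells at 4 h (50.1%), and 24.8% and 32.1% for the interactions at 4 and 8 h (49.5% and 50%). Its median over all genes was -0.10 for MST-312 cells at 4 h and -0.19 and -0.16 for these interactions. Cyclic loess gave 61.2% for the interaction at 8 h. With an estimated correlation 100 of the 178 list shifts were not called, and with fry, which does not compare with other genes, 178 were called. Median scaling and cyclic loess each ended 9 list calls, only the groups of the comparison 8, the mean of passing probes 6, array weights and the stricter detection limit 2 each, and 57 list calls ended over all left-out arrays. Among gene values, calls ended in 11 with median scaling, 5 with the mean of passing probes, 5 without the filter and 45 over all left-out arrays. With the replicate number as a block, the telomere list in untreated cells at 4 h was not called (adjusted p = 0.05695), MYC at 0 h was called (0.0263), and no other call of these results changed. The residual block changed the same calls (0.0544 and 0.0214), and the block within each time ended 1 list and 1 gene call and added MYC at 0 h. Signal over background limits genes undetected in a group, whose ratios are bounds.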

Other observations

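The class of small nucleolar RNAs, its comparison with all genes under each normalization, the test of other RNAs without a poly(A) tail, and the tests of iron shortage and of MYC level for TFRC and SLC11A2 were chosen only after the results were seen. Of 154 small nucleolar RNAs, which guide the modification of ribosomal RNA and other RNAs, 113, 113, 105 and 130 were higher with MST-312 and 7, 4, 6 and 3 lower at 0, 4, 8 and 24 h (median log2 changes 0.93, 0.94, 0.87 and 1.49, camera p from 2.46e-07 to 4.72e-06 with an estimated correlation).

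The rise was not particular to this class, since of 26 other RNAs without a poly(A) tail 23, 24, 22 and 23 were higher and 1 lower at each time, with a lowest median of 1.10, among them RNA28SN5, of the 28S ribosomal RNA, by 3.43, 4.14 and 4.05 at 0, 4 and 8 h (1.42, 1.70 and 2.23 by a second probe), as were 33, 28, 33 and 36 of 48 canonical histone genes. A difference in RNA recovery or quality, or in priming of RNAs without a tail, could raise all of them, as could an effect of MST-312 on their processing, and all of these stay open.

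Host transcription may account for part of the rise of small nucleolar RNAs, most of which are processed from introns. Over 118 pairs with 71 host genes, host medians were 0.32, 0.24, 0.19 and 0.15, below the 0.58 that a host cause would need. The median of small nucleolar RNA minus host was 0.41, 0.63, 0.60 and 1.03. Its two-sided sign-flip permutation p was 2e-05 at 0 h and 1e-05, the smallest the permutations can give, at the others. That p treats pairs that share hosts and arrays as independent, so it measures spread over genes and not over arrays. At 0 h the median missed the bound of 0.58 for excluding a host cause, and mature host transcripts need not follow transcription. Raised background common to all probes is argued against as the whole cause by protein-coding probes undetected on every array. Their median raw rise was at most 0.0863 (SD 0.0858 over the numbered pairs) of that of the small nucleolar RNAs, where this cause would need over 0.5. They cannot decide about genomic DNA, against which the labels' DNase I step acts, since probes lifted to detection were left out of that set. Genomic DNA thus stays open. Normalization as the whole cause is argued against as well. Each of 5 alternatives left at least 89.4% of the calls in place and kept the median of the class above that of all genes by at least 0.56 (SD at most 0.14, camera p at most 0.00463 with an estimated correlation). Among these, the authors' values and quantile normalization without background correction are not separate checks. The background ratio met the bound of under 0.1 first set for excluding that cause, but by less than its SD. The share of calls left in place missed the 90% first set for excluding normalization. This reading was taken after the values were seen, so a partial share of background or normalization stays open.

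TFRC, the transferrin receptor, and SLC11A2, an iron transporter, have transcripts with iron-responsive elements, and TFRC was higher with MST-312 by 1.42, 2.16, 1.47 and 0.84 and SLC11A2 by 1.45, 1.77, 1.99 and 2.01 at 0, 4, 8 and 24 h. MYC is known to raise TFRC. A higher level of MYC transcript is argued against as the cause at 0, 4 and 8 h, where it differed by -0.23, 0.0553 and 0.03 (log2, at most 0.10 by its second probe). This cause stays open at 24 h, where MYC was higher by 0.38 (0.24 by the second probe), a call lost with median scaling (adjusted p = 0.0931). MYC protein was not measured here, so a cause through the protein stays open at all 4 times. A shortage of iron in treated cells might raise TFRC and SLC11A2, but hypoxia-inducible factor targets, which would also rise, were not called at any time (lowest camera adjusted p = 0.254). Lack of a call does not show that they did not rise. The list of 11 iron handling genes that holds TFRC and SLC11A2 was not called either (2, 3, 2 and 3 rises and 6, 4, 3 and 5 falls at the 4 times). Its members need not move the same way in a shortage, so this list cannot decide. CDC14A, 1 of whose transcripts carries an iron-responsive element, had log2 values of -0.38 at 0 h (adjusted p = 0.0427) and 0.23, 0.13 and -0.15 later, none higher by the test. This argues against a shortage of iron but rests on 1 gene, with the transcript read by its probe unknown, so that cause stays open. A fault of single probes could not be tested with 1 detected probe per gene, whose lowest change was 0.84.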
